A study of Drosophila melanogaster with 3 samples.

How the data were processed

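Chromatin from whole mixed-sex *Drosophila melanogaster* embryos aged 0 to 24 hours, of a line expressing CG12659 with a C-terminal GFP, was fragmented by sonication to a size range of 200 to 800 bp and precipitated with an anti-GFP antibody, per the labels. There were 3 biological replicates in 1 group, numbered as in the labels. Whether they came from separate embryo collections is not stated beyond the word biological. The p-values come from tests over regions or genes and do not measure the spread between replicates. The antibody field of the labels names CG12659 while the description names anti-GFP, and the description was followed.

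The authors deposited region lists in narrowPeak format. Per the file notes, regions were called on each replicate and on the 3 replicates together (the pooled list) against 1 control alignment, which was not analysed here, and a reproducible set was then kept by an irreproducible discovery rate (IDR) step. The aligner, peak caller, versions and IDR threshold are not given in the sources used here. The deposited signal value per region is a score of the authors' peak caller whose scale differs between lists, so it was used only within a list. The deposited −log10 q-value per region was not tested, since 8550 of the IDR peaks share the maximum of 4.23. Each IDR peak was found with the same coordinates and summit in the pooled list, and the set was exactly the 8952 regions of highest signal there. Regions can overlap, and 126 IDR peaks repeat the coordinates of another. The lists hold no read counts, so depth per sample was unknown. Replicates 1 and 2 had 616 regions of identical coordinates and the other pairs none. No list was identical to another, and each replicate was counted.

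All comparisons used the dm6 lists with the Ensembl release 115 annotation (BDGP 6.54) and the release 6 genome sequence. The dm3 lists were only counted, and no coordinates were converted. Coordinates are 1-based. Transposable elements were left out of the gene annotation, leaving 18164 genes on 6 arms, 13945 of them protein-coding. A promoter peak had its summit within 500 bp of any annotated TSS. Other summits were assigned to 5' UTR, coding sequence, 3' UTR, intron, other exon or intergenic sequence in that order. The background was the 18483 pooled regions that overlapped no IDR peak.

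Replicates were compared by the share of the 8952 highest-signal regions of 1 that overlapped those of another by 50% of the shorter region, against 1000 random draws from each list. Shares were compared by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over feature classes, arms or gene lists. Intervals of shares are exact (Clopper-Pearson) at 95%, and cover counting error only. Signal ratios were tested with 100000 permutations. For 6-mers and motifs, presence within 50 bp of the summit was compared with presence within 50 bp of a point 300 bp away on a side drawn at random, by exact McNemar test.

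The 29 gene lists, the motifs, the tests and the alternatives were fixed before the data were examined. A list gave members by symbol, by a symbol pattern or by biotype, and was tested with at least 5 members. The names lat, calypso, Dpt, dys and nos matched no gene and were left out. Named genes were those at the 25 highest-signal promoter peaks found among the highest regions of all 3 replicates, with the divergent partner, and the 5 highest peaks elsewhere; 1 of the promoter peaks is not reported here. The tagged gene, the 4 members with the strongest promoter peak of each called list, up to 2 of each other list, the 10 6-mers with the smallest p and every fixed motif were named too. Members without a peak that are named were chosen after their values were seen.

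Alternatives were the stronger part of the IDR peaks by signal, each replicate left out in turn, TSS distances of 200 and 1000 bp, other overlap rules, other backgrounds, windows of 25 bp and a divergent distance of 500 bp. With a replicate left out, the IDR step was not repeated. The set was then those of the 8952 highest regions of 1 remaining replicate that overlapped those of the other. It held 7530, 7509 and 7771 regions without replicates 1, 2 and 3, so a count or call can change with set size alone. The canonical TSS of each gene, and the eggshell list without Cp190 and Cp110, were added after seeing the data. Where a table had an empty cell, 0.5 was added to each cell for the odds ratio in these alternatives. The tests were tried on simulated data: of 200 simulated lists of 50 genes with peaks at 80% against 42% of 14000 genes, 100% had a p below 0.05, as had 4% of unchanged lists, and a 6-mer put into 10% of 4000 simulated summits had the smallest p of 2080. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.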

Results

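The experiment mapped where the CG12659 protein sits on the genome of *Drosophila melanogaster* embryos. CG12659 is a small protein with a YL1-type C-terminal domain, the fly counterpart of the INO80C subunit of the INO80 chromatin-remodelling complex. A transgenic line that stably expressed CG12659 fused at its C terminus to GFP was used, and chromatin bound by the fusion protein was recovered from whole embryos of mixed sex, aged 0 to 24 hours, with an antibody against GFP (ChIP-seq). There were 3 biological replicates in 1 group. The deposited data were lists of enriched regions, so depth per sample was unknown and no interval that needs it was given. The authors' set of regions reproducible between replicates (the IDR peaks, for irreproducible discovery rate) held 8952 peaks on the dm6 build. The peaks had a median width of 490 bp and covered 3.38 Mb in 7815 separate stretches. The signal value per region was the authors' own and was used only to rank and describe regions within a list.

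The first comparison asked how far the 3 replicates marked the same places. Among the 8952 highest-signal regions of each replicate, 86.9% were shared between replicates 1 and 2, 83.5% between replicates 1 and 3, and 83.6% between replicates 2 and 3. The mean was 84.7% ± 1.94 (SD, 3 pairs), against 23.3% for regions drawn at random from the same lists. The permutation p was 0.001 for each pair, the smallest that 1000 draws can give. Of the IDR peaks, 8680 (97.0%) overlapped a region in the list of every replicate, and 7037 (78.6%) overlapped 1 of the highest regions of all 3. Across the IDR peaks the signal of 2 replicates had Spearman's rho of 0.849 (replicates 1 and 2), 0.820 (1 and 3) and 0.831 (2 and 3). These are correlations across regions, which are not independent replicates, over 8848, 8731 and 8718 regions. The IDR peaks were kept for being reproducible between these same replicates. Their overlap with the replicate lists and these correlations were therefore partly fixed by that choice.

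The next question was which parts of the genome carried peaks. Promoters dominated: 5716 IDR peaks, 63.9% (95% exact interval 62.8 to 64.8), had their summit within 500 bp of an annotated transcription start site (TSS). Of the 18483 other regions of the pooled list, 22.8% did so, an odds ratio of 5.99 (5.67 to 6.33) whose Fisher's exact p was too small to be represented in double precision. In the highest regions of the single replicates the promoter share was 63.2% ± 2.71 (SD, n = 3). Random placement on the same arms gave 13.6%. Introns held 25.7% of the IDR peaks and 48.1% of the other regions, and intergenic sequence held 8.71% and 20.8%. These and the following classes hold only summits over 500 bp from any TSS, since nearer summits in exons or introns were counted as promoter. Coding sequence so defined held 19 IDR peaks (0.212%) against 3.30% of the other regions. The 3' UTRs held 0.693% against 3.39%, the 5' UTRs 0.369% against 0.920% and other exons 0.424% against 0.774%. Each of these shares differed from the other regions by two-sided Fisher's exact test, with the largest adjusted p at 0.000601 for other exons over the 7 feature classes.

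**Figure D1:**
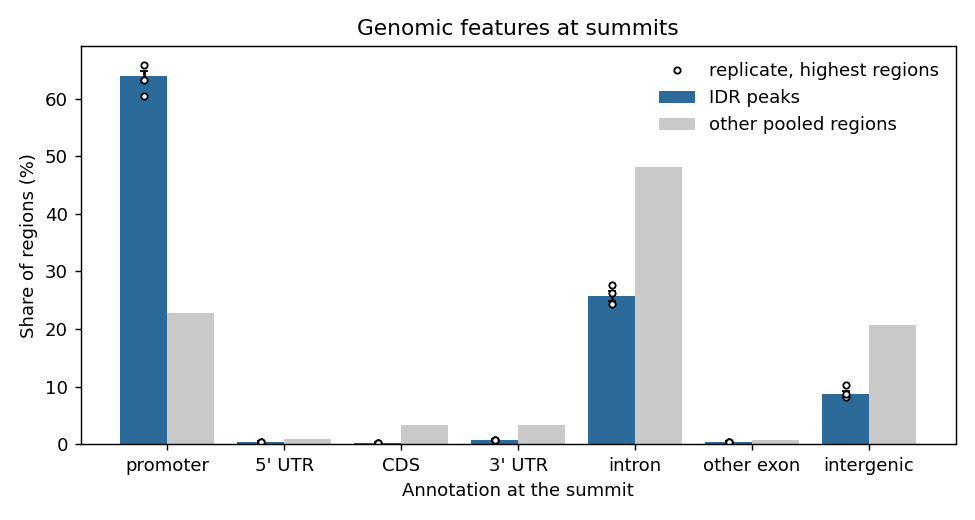
Share of regions in percent by the annotation at the summit, for IDR peaks (blue, with exact 95% intervals), for the other regions of the pooled list (grey) and for the highest regions of each replicate (open points). Promoters held 63.9% of IDR peaks and 22.8% of the other regions, and the 3 replicates lay between 60.4% and 65.9%.

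Promoter summits lay mostly just upstream of the TSS. Of the 5716 promoter peaks, 4015 (70.2%) had the summit upstream, with a median position of -52 bp and quartiles at -141 and 15 bp. Within 200 bp of the TSS lay 4532 of them (79.3%).

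**Figure D2:**
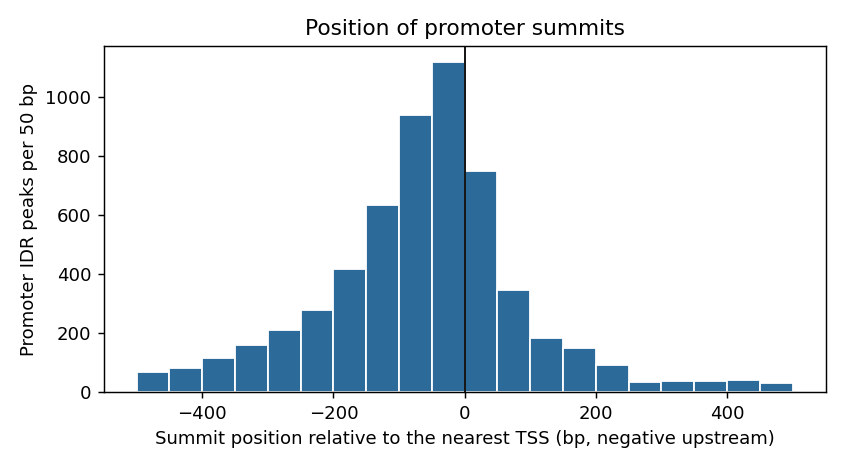
Number of promoter IDR peaks per 50 bp by the position of the summit relative to the nearest TSS, in bp, with upstream positions negative and the TSS at the vertical line. Upstream positions held 70.2% of the peaks, and the median was -52 bp.

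Peaks of higher signal were more often at promoters. The promoter share fell from 73.5% in the 3000 highest regions of the pooled list to 18.9% in the 3000 lowest, while the intron share went from 19.2% to 48.0%. Within the IDR set the median signal was 386 at promoters and 301 elsewhere, a ratio of 1.29 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The ratio was 1.38 ± 0.0932 (SD, n = 3) with the signal of the single replicates.

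**Figure D3:**
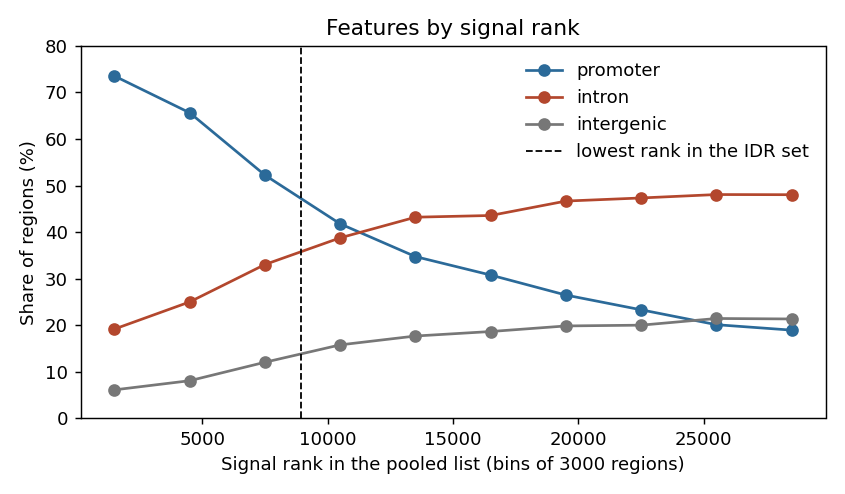
Share of promoter, intron and intergenic summits in percent in bins of 3000 regions of the pooled list, ordered by signal from the highest on the left. The promoter share fell from 73.5% to 18.9%, and the dashed line marks the lowest rank in the IDR set, 8952.

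The strongest peaks named the following genes. The 2 promoter peaks of highest signal lay at CG14100 (3L:19590380-19590863, signal 5705, rank 3) and at Ugalt, a UDP-galactose transporter gene (X:2703649-2704129, signal 5615, rank 4). Genes of mitochondrial translation among the 25 were mRpL41 (signal 4133, rank 8), mRpS10, which shares a divergent promoter with the methyltransferase gene Art3 (signal 3779), and mRpS23, which shares a promoter with CenG1A (signal 3734). PNPase, which encodes polynucleotide phosphorylase, had a peak of signal 3780. Chro, which encodes the interband protein Chromator, and Ssl1, which encodes a subunit of the transcription factor TFIIH, shared a peak of signal 3721. Further peaks among the 25 highest at promoters lay at CG1888 (signal 3826, rank 12), px (signal 3773, rank 15), Fkbp14, CG18549, Tcs5 with the ESCRT-III gene CHMP2B, Tina-1 and CG31145. Others lay at Pal1 with Pdrg1, CG8320 with the peroxisome gene Pex11ab, lncRNA:CR44339, CG9147 with Fbw5, the casein kinase gene gish, and Gapdh2, a glycolytic enzyme gene. The last 4 lay at CG18428 with the cap-binding protein gene eIF4EHP, CG13390 with CG17294, CG1635 and the bZIP factor gene Atf3, down to a signal of 3027 at rank 35.

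Peaks away from a TSS included the highest of all. It lay at 2L:480561-481347 in an intron of ush, which encodes a GATA cofactor, 1399 bp from the nearest TSS, that of cbt, with a signal of 6549. The second lay in an intron of CG11050 (2L:6612417-6612978, signal 5724). The others of the 5 highest lay in an exon of lncRNA:Vinr (X:12750796-12751692, signal 4946), in an intron of Trl, the GAGA factor gene (3L:14759248-14759800, signal 4609), and in intron sequence within the high mobility group genes HmgD and HmgZ (2R:21703071-21703724, signal 4223).

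Divergent promoters carried peaks far more often than others. Of 5052 protein-coding genes with a TSS within 1000 bp of that of a gene pointing the other way, 3612 (71.5%) had an IDR peak at a TSS, against 2291 of 8893 other protein-coding genes (25.8%). The odds ratio was 7.23 (6.69 to 7.81) by two-sided Fisher's exact test, with a p too small to be represented. In the single replicates the shares were 70.4% ± 1.39 and 25.3% ± 1.34 (SD, n = 3). A partner's TSS can lie within 500 bp of the same summit, so 1 peak can count for both genes of a pair.

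Gene groups separated sharply. Of all 13945 protein-coding genes, 5903 (42.3%) had an IDR peak at a TSS, and 18 of the 29 gene lists tested differed from the other genes at an adjusted p below 0.05 (two-sided Fisher's exact test, Benjamini-Hochberg over lists): 8 were higher and 10 lower. Genes of protein synthesis carried peaks most often among the larger lists. Among cytosolic ribosomal protein genes 86 of 92 (93.5%) had a peak (adjusted exact p = 1.51e-24), with RpL7 (signal 2945), RpS27 (2121), RpL34b (2018) and RpL14 (1972) the strongest. The 6 without a peak were RpL10Aa, RpL22-like, RpL37-2, RpS10a, RpS19b and RpS28-like. Among mitochondrial ribosomal protein genes 60 of 73 (82.2%) had one (adjusted exact p = 1.88e-11), led by mRpL41, mRpS10, mRpS23 and mRpL23 (signal 2443). Of the translation factor genes 37 of 52 (71.2%) did (adjusted exact p = 8.14e-05), led by eIF4EHP, eIF6 (signal 2823), eEF1gamma (1592) and eIF1 (1492).

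Genes of cell division and of chromatin were high as well. Of the cell cycle and DNA replication genes 29 of 34 (85.3%) had a peak (adjusted exact p = 1.74e-06), led by CycE (signal 1213), which encodes cyclin E, Dp (1204), the partner of E2F, the ribonucleotide reductase gene RnrS (985) and dpa (917), which encodes a subunit of the replicative helicase. In the Polycomb and trithorax groups, which keep developmental genes off or on, 20 of 21 genes (95.2%) had one, again at an adjusted exact p of 1.74e-06, led by brm (2245), ph-p (1889), E(z) (1450) and Sfmbt (1019). Sce was the member without a peak. Among the stronger peaks 12 of the 21 had one (57.1% against 28.8% of other genes, adjusted exact p = 0.0155). Without replicates 1, 2 and 3 the counts were 16, 16 and 18 of 21, and the list was still called each time. Of the insulator and architectural protein genes 13 of 16 (81.3%) did (adjusted exact p = 0.00425), led by Chro, Cp190 (2157), Dref (1161) and M1BP (1004). The M1BP peak had no matched signal in replicate 3.

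Energy and protein turnover genes were also called. Oxidative phosphorylation genes had a peak in 56 of 84 cases (66.7%, adjusted exact p = 3.44e-05), led by ND-ASHI (signal 1207), ND-MWFE (977), ATPsynC (968) and ND-51 (957). Of the 28 without a peak, most were paralogs such as ATPsynbetaL, COX4L and UQCR-14L. Proteasome subunit genes had one in 29 of 48 cases (60.4%, adjusted exact p = 0.0229), led by Rpn6 (922), Rpn3 (888), Rpn5 (755) and Rpn13 (732). Of the 19 proteasome genes without a peak, most were paralogs such as Prosalpha1R, Prosalpha4T1 and Rpt3R. Restricted to genes with any pooled region at a TSS, 11 lists were called, and neither of these was among them (adjusted exact p = 0.165 for oxidative phosphorylation and 0.192 for the proteasome). The proteasome odds ratio was 2.14 over 34 members there and 2.08 over all 48, and that of oxidative phosphorylation was 1.72 over 68 members and 2.74 over all 84. The cell cycle (adjusted exact p = 0.142), insulator (adjusted p = 0.477), anterior-posterior segmentation (adjusted p = 0.159) and hemocyte (adjusted p = 1) lists were not called there either, while the muscle (adjusted p = 0.00490) and tracheal (adjusted p = 0.00890) lists were, as lower. The proteasome call was also lost with TSSs within 1000 bp (adjusted exact p = 0.0726).

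Hox, segmentation and neuroblast genes seldom carried a peak. Of the 12 Hox cluster genes only bcd, the maternal anterior determinant that lies in that cluster, had one (signal 444, adjusted exact p = 0.0305). Leaving out any replicate ended this call (adjusted exact p = 0.0602, 0.0547 and 0.0574 without replicates 1, 2 and 3). The count stayed at 1 of 12 there, while the share of other genes with a peak fell from 42.4% to 37.2%, 37.9% and 39.0% in those smaller sets. In 3 other alternatives the call was lost too, with the highest adjusted exact p at 0.274 among the stronger peaks. Of 29 anterior-posterior segmentation genes 3 had a peak (adjusted exact p = 0.000601): ptc (signal 307), cad (198) and hry (186). Without replicate 1, and without replicate 2, 1 of the 29 did, among the stronger peaks 0, and without replicate 3 it was 2. Of 18 neuroblast and proneural genes 2 did (adjusted exact p = 0.0140): numb (1368) and brat (527). That call was lost among the stronger peaks (adjusted exact p = 0.174) and with TSSs within 200 bp (0.0651) or 1000 bp (0.0831). Of 22 hemocyte and immunity genes 4 did (adjusted exact p = 0.0461): Rel (621), crq (518), Dif (258.4) and ush (258.2), and without replicate 2 it was 2 of 22. Leaving out replicate 3 ended that last call (adjusted exact p = 0.0756), with 4 of 22 still carrying a peak. The stronger peaks alone (adjusted exact p = 0.0901), TSSs within 200 bp (0.146) and the canonical TSS only (0.0713) ended it too. Among genes with a pooled region the direction of the hemocyte list turned, with 4 of 5 against 73.1% (odds ratio 1.47, adjusted exact p = 1).

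Cuticle, chemoreceptor, testis and eggshell genes had the lowest shares. Of 118 cuticle protein genes 1 had a peak, Lcp9 (signal 286, adjusted exact p = 8.59e-26), and 0 did when any replicate was left out. With TSSs within 1000 bp 4 of the 118 had one. Of 179 chemoreceptor genes 5 did (adjusted exact p = 8.50e-34), the strongest at Ir60e (557), Ir60b (299.5), Gr63a (290) and Gr97a (282), and without replicate 2 it was 3 of 179. With TSSs within 200 bp 0 of them did, among the stronger peaks 1 and with TSSs within 1000 bp 8. Of 27 testis genes Mst85C alone did (580, adjusted exact p = 3.71e-05), at a peak that overlaps the Rel peak. With TSSs within 1000 bp 2 of the 27 did. In the eggshell and yolk list 1 of 16 did (adjusted exact p = 0.00757), and that gene was Cp190, an insulator protein gene matched by its symbol, as was Cp110, which is a centriolar gene. Among the stronger peaks that list was not called (adjusted exact p = 0.0901). Among genes of non-coding RNAs, 27 of 290 tRNA genes (9.31%, adjusted exact p = 1.72e-23) and 25 of 269 snoRNA genes (9.29%, adjusted p = 7.83e-22) had a peak, against 35.4% and 35.3% of all other genes. These shares moved with the TSS distance: they were 2.07% and 4.09% within 200 bp, and 19.0% and 29.4% within 1000 bp, where 39.6% and 39.5% of all other genes had a peak, and both stayed lower. The strongest were at tRNA:Tyr-GTA-1-8 (2025), tRNA:Trp-CCA-2-2 (1456), tRNA:Phe-GAA-1-2 (882) and tRNA:His-GTG-1-3 (839). The snoRNA peaks included that of snoRNA:U49:66Da (1972), which is the RpL14 peak, that of snoRNA:Psi28S-2949 and snoRNA:Or-aca5 (1535), and that of snoRNA:Or-CD11a (1492), which is the eIF1 peak.

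The other 11 lists did not pass the threshold. Dosage compensation genes had a peak in 6 of 7 cases (adjusted exact p = 0.0715), with msl-2 (signal 428) and msl-3 (391), and all 7 had one without replicate 3 (adjusted p = 0.00284). Heat shock and chaperone genes had one in 13 of 28, with Hsp83 (1588) and Hsc70-5 (1538), and none of the 6 Hsp70 genes of the list had one. The Hsp70 genes are near-identical copies, and how reads from such copies were treated is not given in the sources used here. Shares were 10 of 20 for the Notch pathway and E(spl) complex, with E(spl)m3-HLH (1489) and gro (1457), and 7 of 13 for the embryonic germline, with bgcn (1112) and gcl (807). They were 5 of 21 for dorsal-ventral patterning, with tin (992) and Ance (425) and an adjusted exact p of 0.158 that became 0.0412 without replicate 2, where 3 did, 4 of 20 for neurons, with elav (2407) and Syx1A (414), and 3 of 11 for glia, with moody (1784) and loco (365). Muscle genes had 7 of 25, with Msp300 (1435) and sls (1019.0), tracheal genes 2 of 10, with trh (974) and bnl (213), and gut and fat body genes 3 of 14, with fkh (1288) and apolpp (536). Without replicate 1 the counts were 3 for dorsal-ventral patterning and 2 each for glia and for gut and fat body, without replicate 2 that of gut and fat body was 2, and without replicate 3 that of glia was 2. The tracheal count was 1 with any replicate left out. Of the snRNA genes 6 of 32 had a peak, with snRNA:U6:96Ab and snRNA:U6:96Ac at a shared peak of 375. With TSSs within 200 bp the dosage compensation (adjusted exact p = 0.0143), dorsal-ventral (0.00437) and neuron (0.00671) lists passed, as did the snRNA genes among the stronger peaks (0.0413) and the dosage compensation list with the canonical TSS only (0.0304).

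**Figure D4:**
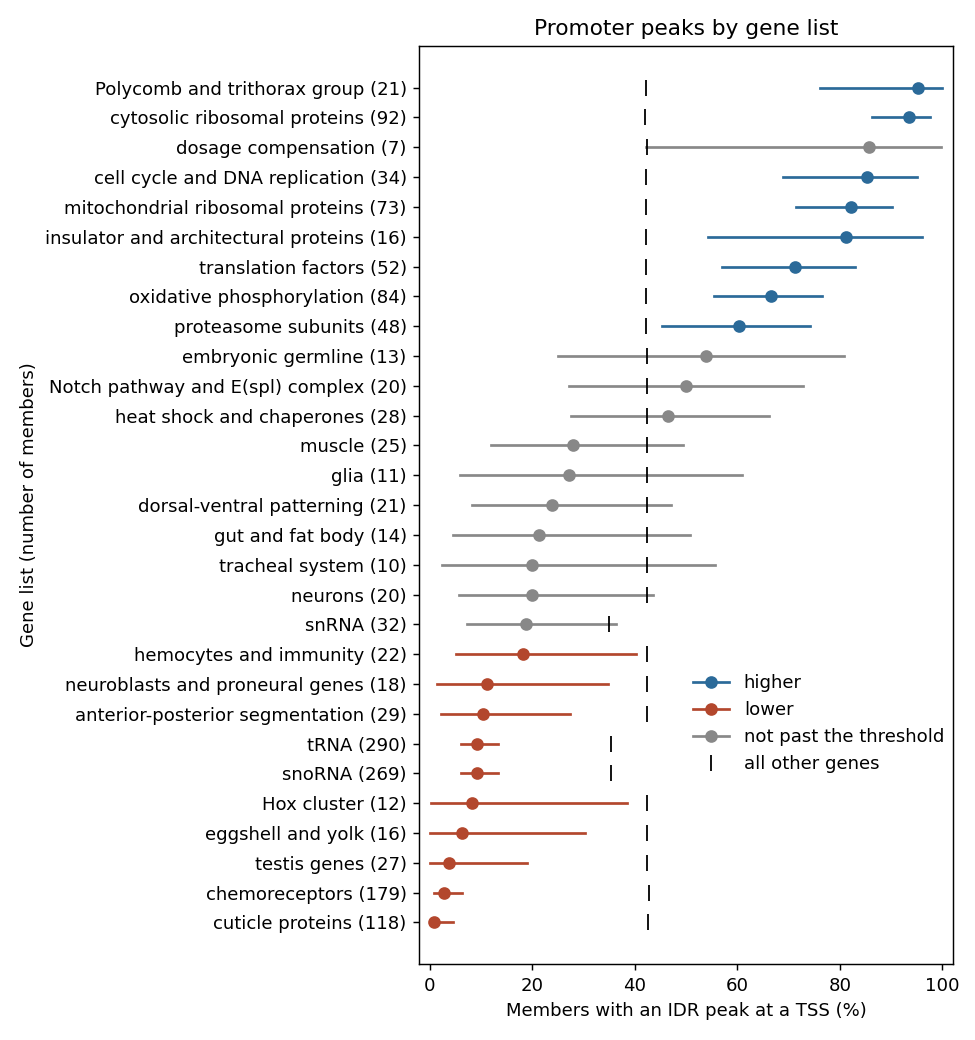
Share of members with an IDR peak at a TSS in percent for each gene list, with the number of members in brackets, exact 95% intervals as lines and the share of all other genes as a black tick. Lists higher and lower at an adjusted p below 0.05 are blue and red. Ribosomal protein and Polycomb and trithorax genes lie at 93.5% and 95.2%, and cuticle protein genes at 0.847%.

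Sequence at the summits differed from sequence 300 bp away. Of 2080 6-mers, counted on both strands within 50 bp, 1466 differed at an adjusted p below 0.05 (exact McNemar test, two-sided), 512 higher and 954 lower at the summit. The 10 with the smallest p among those higher were AAATAT (31.1% of peaks against 17.1%), AAAATA, TTAAAA, TAAATA, AATATA, ATATTA, ATTTTA, ATTTAA, TATCGA and TAAAAA. All but TATCGA (12.2% against 4.94%) consist of A and T alone.

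Motifs of broadly active promoters were more frequent at summits. The DNA replication-related element (DRE, TATCGATA), bound by Dref and overlapping the site of BEAF-32, lay at 3.59% of summits and 0.882% of flanks (adjusted exact p = 1.12e-35). The shorter BEAF-32 element CGATA lay at 21.5% and 12.7% (adjusted exact p = 1.53e-55). The M1BP site GTCACACT lay at 2.74% and 0.570% (adjusted exact p = 1.02e-31), Ohler motif 6 at 2.35% and 0.894% (adjusted p = 2.56e-14) and Ohler motif 7 at 7.94% and 3.76% (adjusted p = 6.83e-33). At promoter peaks the DRE reached 5.39% of summits against 1.22% of flanks, and at peaks elsewhere 0.402% against 0.155% (adjusted exact p = 0.160). CGATA (adjusted exact p = 0.914) and Ohler motif 7 (0.677) did not pass at peaks elsewhere either. M1BP (0.278% against 0.0309%, adjusted exact p = 0.0430) and Ohler motif 6 (1.30% against 0.587%, adjusted exact p = 0.0127) did pass there. The insulator motif of CTCF lay at 1.17% against 0.290% (adjusted exact p = 4.18e-12) and that of Su(Hw) at 0.938% against 0.525% (adjusted p = 0.00283). The TATA box lay at 19.9% against 11.2% (adjusted exact p = 1.53e-55). Lower at summits were the GAGA motif of Trl (1.16% against 2.93%, adjusted exact p = 5.91e-17), the CA repeat (1.34% against 4.18%, adjusted p = 2.02e-31) and the E-box CACGTG (0.815% against 1.44%, adjusted p = 0.000183). The CACGTG call was lost among the stronger peaks (adjusted exact p = 0.0767) and the Su(Hw) call against matched pooled regions (0.127). The CTCF ratio of 4.04 was 2.27 without replicate 2, 2.56 without replicate 3, 2.60 among the stronger peaks, 7.71 within 25 bp of the summit and 1.64 against matched pooled regions. In that last comparison M1BP lay at 2.46% of IDR peaks and 0.819% of pooled regions, and the GAGA motif at 1.16% and 1.84%. Both differences were smaller than against flanks, and both were still called. At promoter peaks, set against upstream flanks alone, the CA repeat lay at 1.45% of summits and 1.63% of flanks (adjusted exact p = 0.585) and CACGTG at 0.892% and 1.15% (0.279). In the same comparison the TATA box lay at 17.7% and 16.8% (adjusted exact p = 0.283) and Su(Hw) at 0.840% and 0.542% (0.142).

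The remaining motifs did not pass the threshold over all peaks. That of Pho, a DNA-binding Polycomb group protein, lay at 2.18% of summits and 1.75% of flanks (adjusted exact p = 0.0765). Values were 5.16% and 4.88% for CAGCTG, 3.51% and 3.09% for CATATG, 9.04% and 9.24% for the Initiator, and 0.447% and 0.570% for the Zelda motif. They were 3.06% and 3.13% for GATA, 2.96% and 2.79% for STAT, 0.190% and 0.145% for Ets, and 2.55% and 2.71% for the heat shock element. CAGCTG was higher at the summits of promoter peaks (6.44% against 5.18%, adjusted exact p = 0.00796) and lower at those of peaks elsewhere (2.90% against 4.54%, adjusted p = 0.00279), where STAT was higher (3.65% against 2.29%, adjusted p = 0.00516). Without replicate 3 CAGCTG (adjusted exact p = 0.0186) and Ets (0.0349) passed as higher, and without replicate 2 the Zelda motif (0.0192) passed as lower. The Initiator passed as lower among the stronger peaks (adjusted exact p = 0.0164) and against matched pooled regions (0.000398).

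**Figure D5:**
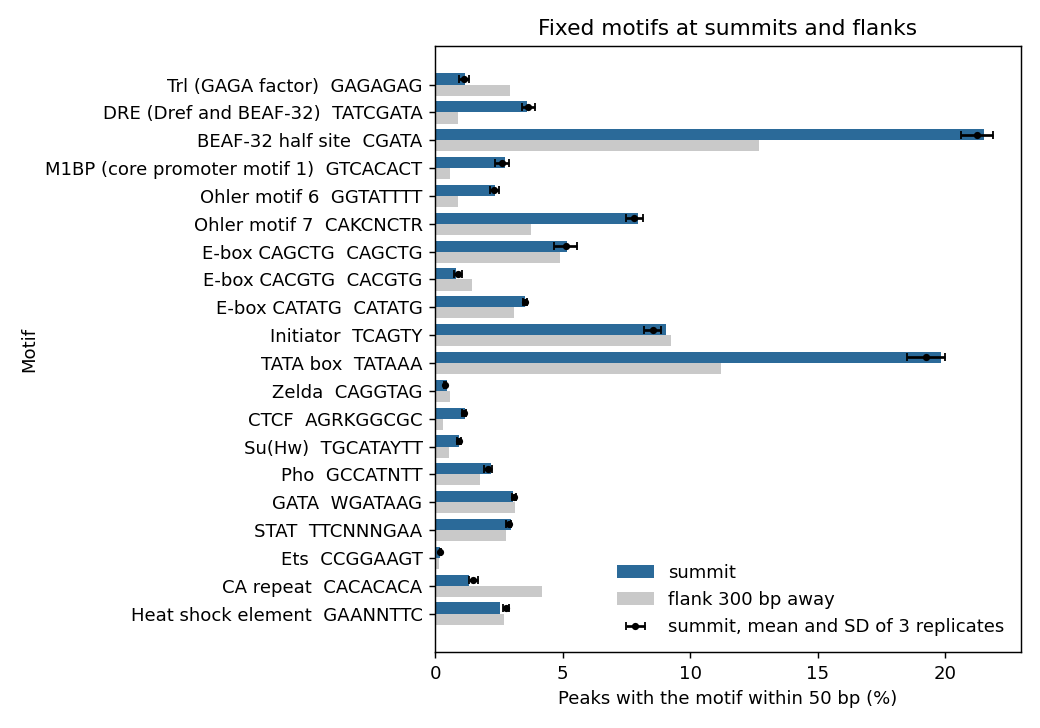
Share of IDR peaks in percent with each fixed motif within 50 bp of the summit (blue) and of a point 300 bp away (grey), with the mean and SD over the highest regions of the 3 replicates as black points. The DRE lies at 3.59% of summits and 0.882% of flanks, and the GAGA motif at 1.16% and 2.93%.

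Peaks were spread over all arms. The X chromosome held 1644 IDR peaks (18.4%) and 19.4% of the other pooled regions, an odds ratio of 0.937 (0.878 to 0.999) with a Fisher's exact p of 0.0491 that became 0.0736 after adjustment over the 6 arms. Set against the X share of arm length, 17.6%, the X share of peaks lay on the other side (exact binomial p = 0.0537), so the direction for X depended on the background. The unadjusted Fisher's exact p against the other regions was 0.307 without replicate 1, 0.0463 without replicate 2 and 0.000555 without replicate 3, and among the stronger peaks, 17.4% of which lay on X, it was 0.00131. Arm 2R held more peaks than other regions (19.2% against 17.3%, adjusted p = 0.000367), as did 3R (23.0% against 21.6%, adjusted p = 0.0209), and 3L held fewer (20.3% against 22.4%, adjusted p = 0.000367), all by Fisher's exact test. The share of 3R lay below its 24.0% of arm length, so its direction depended on the background too. Set against their shares of all annotated TSS positions, 20.6% for 2R and 19.3% for 3L, these 2 arms changed direction as well. No test was made against TSS positions.

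The CG12659 gene itself (FBgn0040929, X:8590775-8591729, minus strand) had IDR summits upstream of its TSS at X:8591951, 222 bp away, with a signal of 651 (rank 1533 of 8952), and at X:8592150, 421 bp away, with a signal of 278 (rank 5976). In the single replicates the nearer region ranked 1349, 2168 and 1526 for replicates 1, 2 and 3. A stronger summit, of signal 852, lay at X:8588834, beyond the other end of the gene.

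The lists on the older build, dm3, held 8848 IDR peaks, 30000 regions each for the pooled list and replicates 1 and 2, and 23687 for replicate 3, against 28466 for replicate 3 on dm6.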

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

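On the dm3 build 19 IDR peaks lie outside the 6 arms, on heterochromatic scaffolds of that build: 7 on 2RHet, 5 on 3LHet, 4 on 3RHet, 2 on XHet and 1 on 2LHet, with signal values up to 578. They were picked out as signal outside the 6 arms of dm3. No dm6 list had a region off the 6 arms. Coordinates were not converted, so whether the same loci are among the dm6 peaks is unknown. The control alignment was not analysed here, so no control level is given.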

How the results depend on the processing

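Of 50 alternative values of the main comparisons, 47 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times the count reported: the promoter share lay between 50.6% and 71.8%, the divergent odds ratio between 5.14 and 8.92, the signal ratio between 1.05 and 1.29 and the 6-mers called between 1040 and 1466. The values of single gene lists include 29 from the setting without Cp190 and Cp110, which altered only the eggshell list. The other lists kept their main counts there by construction, so their values could hardly change. Of 257 values of single gene lists 225 stayed on their side of the threshold in the same direction, 20 lost a call, 9 gained one and 3 changed direction. Of 120 values of motifs 103 stayed so, 2 lost a call, 5 gained one and 10, all of motifs not called, changed or lost their direction. The X share was 18.4% against arm length, where its direction reversed, and ranged from 17.8% to 18.4% when replicates were left out, where the unadjusted Fisher's exact p went from 0.0491 to 0.307 without replicate 1. Restricted to genes with a pooled region at a TSS, 11 gene lists were called in place of 18; that setting leaves fewer genes, and 4 lists with fewer than 5 members could not be tested. There the log2 odds ratio of the hemocyte and immunity list reversed to 0.56 (adjusted exact p = 1). That of the Notch list was -1.08 with TSSs within 200 bp, and that of the heat shock list -0.21 with the canonical TSS only. The ratio of summits to flanks was 0.850 for CAGCTG, 0.960 for STAT and 1 for GATA among the stronger peaks, from 0.958 to 1.13 for GATA when replicates were left out (1 without replicate 1), and 1.02 for the Initiator and 0.989 for Pho within 25 bp. Against matched pooled regions it was 0.996 for CATATG, 0.949 for STAT and 1 for Zelda. For the X share, these lists and these motifs the cause was not tested. With the canonical TSS only, chosen after seeing the data, 17 lists were called and the divergent odds ratio was 7.09. Without Cp190 and Cp110, also chosen after seeing the data, the eggshell list had an adjusted exact p of 0.00126. The lists hold no read counts, so what depth limits could not be measured. No paired analysis was possible because there was 1 group.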

Other observations

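The gene families and the weaker-region and TATA box tests here were chosen after seeing the data. Beyond the fixed lists, 59 families of protein-coding genes sharing the opening letters of their symbol, with at least 10 members outside those lists, were tested by two-sided Fisher's exact test, and 39 differed from all other genes at an adjusted p below 0.05 (19 higher, 20 lower). Of the Mediator genes (MED) 24 of 25 had an IDR peak at a TSS (adjusted exact p = 2.34e-07), as had 19 of 21 PIG genes of GPI-anchor synthesis (adjusted p = 5.03e-05), 17 of 19 Sec genes of secretion (adjusted p = 0.00018), 18 of 21 nucleoporin genes (Nup, adjusted p = 0.000268) and all 10 EMC genes of the endoplasmic reticulum membrane complex (adjusted p = 0.000723). Peroxin genes (Pex, 13 of 15, adjusted exact p = 0.00235), TBP-associated factors (Taf, 12 of 15, adjusted p = 0.0128) and autophagy genes (Atg, 14 of 20, adjusted p = 0.0343) were high too. The letters pre gave 23 of 24, but these are mod(mdg4) precursors of a single locus and are not independent.

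Of the Cyp genes, mostly cytochrome P450 genes, 7 of 85 had a peak (adjusted exact p = 1.15e-10), and 1 of those was Cyp1, a cyclophilin gene. Values were 2 of 51 for odorant-binding proteins (Obp, adjusted exact p = 1.06e-08), 2 of 35 for Ugt genes (adjusted p = 2.42e-05), 1 of 25 for Osiris genes (Osi, adjusted p = 0.00017), 2 of 29 for ppk channels (adjusted p = 0.00022) and 0 of 19 for accessory gland proteins (Acp, adjusted p = 0.000268). Of the histone genes 3.48% had a peak (adjusted exact p = 4.12e-20), namely His2Av, His3.3A, His3.3B and His4r, which lie outside the repeated histone cluster. The 20 families that did not pass included Tim (5 of 11), Vha (11 of 22), Alg (7 of 11), Klp (5 of 11) and GstE (4 of 14). Clustered copies are not independent, and how reads from identical copies were treated is not given in the sources used here.

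Promoter peaks were frequent in the 8 lists called higher and rare in those called lower. Members of the 8 lists had a divergent neighbour more often (59.0%) than other genes (35.5%), but among genes with no divergent neighbour 110 of 172 members had a peak against 2181 of 8721 others, an odds ratio of 5.32 (3.88 to 7.29), which argues against divergent promoters as the whole account. The 8 lists were chosen for many IDR peaks, so part of this excess was fixed by the choice. Dilution of small cell populations stays open, with values on both sides. Among genes without an IDR peak a weaker pooled region was less frequent in the Hox, segmentation, neuroblast and hemocyte lists together (odds ratio 0.501, 0.263 to 0.956), though in 0 of these 4 lists alone. The cuticle, chemoreceptor, eggshell and testis lists together gave 0.268 (0.184 to 0.389). Among genes with a pooled region an IDR peak was less frequent as well (0.333, 0.141 to 0.786, and 0.0937, 0.0430 to 0.204), in 1 and 2 of the 4 lists alone. These lists were chosen for few IDR peaks, so that second result was partly fixed by the choice. The grouping tried first, 10 developmental and tissue lists called or not, gave 1.21 (0.842 to 1.73) for the weaker regions and 0.272 (0.173 to 0.428) for IDR peaks among genes with a pooled region. Dilution below the reach of the pooled list was not measured. Signal at open promoters whatever the tagged protein could not be tested, since no untagged or other-tag sample was analysed here, and no biological explanation was tested, as there is 1 group.

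Promoter motifs were more frequent at summits, and summits were poor in G and C (37.6% at promoter peaks and 33.3% elsewhere, against 42.5% and 43.4% on the left flank). Against base composition as the account of most motifs, 6 of the 8 motifs called higher had a summit to flank ratio above the 95th percentile of up to 100 anagrams of their own letters, the DRE at 4.06 against 2.71. These anagrams were run on all IDR peaks only, and the CTCF ratio of 4.04 fell to 2.27 without replicate 2 and 2.56 without replicate 3. For the TATA box and Su(Hw), 0 of 2 did, so base composition of the summits may account for those, and against upstream flanks the TATA box had a ratio of 1.05 (exact McNemar p = 0.213). At promoter peaks the DRE had a ratio of 2.63 against upstream flanks (exact McNemar p = 1.63e-21) and of 14.7 against downstream flanks. Divergent promoters were not removed, and there an upstream flank can lie in transcribed sequence of the partner gene. This comparison therefore cannot decide whether flanks in transcribed sequence account for the difference.

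The 7 highest IDR peaks included 5 that lay over 500 bp from a TSS, against 28 of the 100 highest. Of these 5, 2 lay only 516 and 606 bp from a TSS. The cut at 7 is the rank of the last of these 5, so the contrast depends on both cut-offs. Repeated sequence was checked as a candidate explanation. The 50 highest peaks over 500 bp from a TSS had a median of 0% repeated 31-mers within 100 bp of the summit. Midpoints of 50 long transposable elements gave 100%, so the count could find repeats present in the genome sequence used. Copies missing from that sequence could not be counted, and how reads from repeated copies were treated is not given in the sources used here. If such reads were dropped, a value of 0% was fixed in advance. The count therefore cannot decide whether repeated sequence accounts for these peaks. Unannotated start sites stay open and were not tested.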
